A study of Caenorhabditis elegans with 2 samples.

How the data were processed

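LET-607 with a C-terminal GFP-FLAG tag was immunoprecipitated from whole young adult hermaphrodite C. elegans with an antibody against GFP, after sonication, in 2 biological replicates of 1 group, per the labels. Groups and replicate numbers came from the labels' own replicate numbers, and no control group was analysed here.

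The authors deposited 8 peak lists in narrowPeak format, 4 on build ce10 and 4 on ce11. Per the deposited descriptions, relaxed peaks were called on each replicate and on the pooled alignments against 1 control file per build, and the optimal IDR list kept the peaks past the authors' reproducibility threshold. The aligner and the peak caller are not given in the sources used here. The deposited signal per peak (column 7) has no stated scale and was read only within its own list. The deposited −log10 q-value (column 9) was tied at its maximum of 3.65 for 2252 of the 2372 IDR peaks and was not used to rank. The IDR list was found to be exactly the 2372 strongest peaks of the pooled list by signal, which ranged from 78.2 to 13028 with a median of 122. Of these peaks, 73.5% had the median width of 424 bp, so widths were not interpreted, and the 2372 summits lay in 2348 distinct intervals. No read counts were analysed here, so the depth of each library is unknown. Confidence intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

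The ce11 lists were main, since ce11 has the coordinates of the WBcel235 annotation (Ensembl) and of the RefSeq sequence used here. A gene was bound if an IDR summit lay between 1000 bp upstream and 200 bp downstream of the 5′ end of its Ensembl gene model. Of the 1238 peaks with a gene, 364 (29.4%) had more than 1, each of which counted as bound, and the median position of the summits was 244 bp upstream of the 5′ end. Where several genes shared a symbol, the RefSeq symbol of the same WormBase gene was used. Coordinates are 1-based.

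The tests, the 22 gene lists, the 14 fixed sequences and most of the other settings tried were set before the data were examined. Overlap of replicate lists was compared with 1000 random placements within chromosomes, and the share on X with placements over the nuclear genome. Lists were tested by two-sided Fisher's exact tests against all other protein-coding genes with Benjamini-Hochberg adjustment. Sequences on either strand within 50 bp of the summit were compared with windows of equal length centred 300 bp to either side by exact binomial tests of discordant peaks, keeping the larger p of the 2 flanks. All 6-mers, with reverse complements merged, were tested in the same way. Peaks with and without TGACGT were compared by a permutation test of mean rank with 100000 permutations. Genes and peaks are not replicates, so p-values over them describe this peak set and not the spread between animals.

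The genes named were the tagged gene, those in reach of the 20 strongest IDR peaks, and of each list up to 4 bound members with the highest signal, with up to 3 unbound members in alphabetical order for the 4 secretory lists (ER folding, ER-Golgi transport, translocation and N-glycosylation). Of the mitochondrial genes in reach, none is described further. The genes of the 20 strongest nuclear peaks, sec-61.A, tram-1, crt-1 and hsp-4 were added after the values were seen. Housekeeping lists were the ribosomal, proteasome and respiratory lists.

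Other settings, fixed in advance, were a stricter signal threshold, each replicate left out (the 2372 strongest peaks of the other replicate's list), the ce10 lists, other overlap rules, promoter windows of 500 and 2000 bp, the nearest 5′ end only, merged summits, other background genes, genes sharing a summit left out, windows of 25 and 100 bp, a dinucleotide-shuffled background, promoter peaks only and TGACGTGG in place of TGACGT. Leaving out mitochondrial peaks, and peaks within 100 bp of tRNA, snoRNA or snRNA genes, and genes whose window overlaps that of another protein-coding gene, was added after the data were seen.

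The list tests, the sequence and 6-mer tests, the promoter placement and the rank test were tested on simulated data, and the interval overlap against a direct count. With 5 lists raised to an odds ratio of 5, 87.8% of raised lists were called, and 4% of simulated sets without a raised list gave any call. Those sets drew each gene as bound independently, at a higher rate than the 7.76% of the data. In the data, 726 of the 1550 bound genes shared a summit, so these rates may not hold there. A sequence planted in 10% of simulated peaks was recovered as 9.27 percentage points over flanks, and the planted 6-mer ranked 1 by p. The simulated peaks were random genomic windows, so a change of base composition at real summits was not covered. With 40% of simulated peaks moved into promoter windows, 53.0% were measured there against 52.8% expected. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.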

Results

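LET-607 is a C. elegans transcription factor of the CREB3 family, a group of bZIP proteins held in the membrane of the endoplasmic reticulum (ER). Its binding to the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult hermaphrodites, 67 h after release from synchronization as starved first-stage larvae. The animals carried LET-607 fused at its C-terminus to GFP and FLAG tags, and an antibody against GFP was used. There was 1 group of 2 biological replicates, so the questions the design can answer are how well the replicates match and where in the genome the binding lies. The files held peak lists without read counts, so sequencing depth is unknown. The relaxed lists held 26463 peaks in replicate 1, 22592 in replicate 2 and 26789 in the pooled data, and the authors' final list, thresholded on reproducibility between replicates (IDR), held 2372 peaks on build ce11. The per-peak signal is the authors' own value, without a stated scale, and was used only to rank peaks within a list.

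The strongest binding sites were found in both replicates. The peaks at ile-2 and trap-2, at serp-1.1, at sec-61.G and at trap-3 and sec-61.B, which were the 4 strongest on the nuclear chromosomes, held ranks 3, 4, 5 and 6 in each replicate's relaxed list. Of all IDR peaks, 2356 (99.3%) overlapped a relaxed peak of both replicates, in lists that were many times longer. The IDR list was selected on reproducibility and is the top of the list pooled from the same replicates. That overlap was therefore largely fixed by the selection. Only 69.5% (exact 95% interval 67.6 to 71.4) overlapped one of the 2372 strongest peaks of each replicate, a limit that by itself leaves out weaker peaks. In 4 equal groups by IDR signal, from the strongest down, that share was 99.5%, 96.5%, 65.8% and 16.36%. All lists compared were cut at the same number of peaks, and the pooled list came from both replicates. A fall towards the weaker groups was therefore built into this measure. Of the relaxed peaks of replicate 2, 55.0% (exact 95% interval 54.3 to 55.6) overlapped a peak of replicate 1 by at least 1 bp, against a mean of 20.03% and a maximum of 20.9% over 1000 random placements. Spearman's rho of signal across 13116 overlapping pairs was 0.545, across peaks, which are not independent replicates. The overlap was 42.6% when each peak had to cover 50% of the other, 31.8% when summits had to lie within 100 bp, and 73.5% for the 2372 strongest peaks of each list, where rho was 0.728.

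Binding was concentrated at the 5′ ends of protein-coding genes and was denser on chromosomes X and III than on V. Of the IDR summits, 1238 (52.2%, 50.2 to 54.2) lay between 1000 bp upstream and 200 bp downstream of a protein-coding gene's 5′ end, against 21.5% for random placements within chromosomes, a ratio of 2.43 (two-sided permutation p = 0.002, the smallest the placements can give). Outside these windows, exons held 5.61% of summits against 22.97% at random, introns 19.4% against 30.6%, and intergenic sequence 18.8% against 21.8% (permutation p = 0.002 each). Other annotated genes held 4.01% against 3.21% (permutation p = 0.044). Chromosome X carried 537 nuclear peaks, 30.3 per Mb, chromosome III 29.8 per Mb and chromosome V 16.54 per Mb. The share of nuclear peaks on X was 22.9% against 17.7% of nuclear sequence (two-sided permutation p = 0.002), and 20.4% when peaks at tRNA, snoRNA or snRNA genes were left out (permutation p = 0.002). The mitochondrial genome carried 23 IDR peaks, among them the 2 strongest of the list, and 212 nuclear peaks (9.03%) had their summit within 100 bp of a tRNA gene.

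Genes of the secretory pathway stood at most of the 10 strongest nuclear peaks. The peak of highest signal (9329; X, 767898 to 768573, ce11) lay between the divergent genes ile-2, a cargo receptor gene of ER-to-Golgi transport, and trap-2, a subunit gene of the translocon-associated complex, with its summit 356 bp and 171 bp upstream of their 5′ ends. The second (signal 8807; X, 15840946 to 15841634) lay 292 bp upstream of serp-1.1, and the third (8248; V, 10896984 to 10897701) 210 bp upstream of sec-61.G, a gene of the ER translocation channel. The fourth (7275; IV, 2388786 to 2389486) lay 308 bp upstream of trap-3 and 462 bp upstream of sec-61.B, and the fifth (5058; X, 6091794 to 6092506) 51 bp upstream of hsp-3, which encodes an ER chaperone of the BiP type. Peaks with signal 4643 at trap-1 and 4456 between enpl-1 (the ER chaperone endoplasmin) and imp-2 held nuclear ranks 7 and 8. Nuclear rank 9 (signal 3018) was held by a peak at bbs-9 and C48B6.10, neither of which is on a secretory list. Further down the first 20 came pdi-1 and pdi-3 (protein disulfide isomerases), calu-1, iff-2, xbp-1 (a transcription factor of the unfolded protein response), srh-70 with ceh-99, trap-4 and tsn-1. Other genes in reach were F32D8.13 at the sec-61.G peak, C14B1.2 at pdi-1 and F54C9.14 at iff-2. So were ubql-1 at pdi-3, ccf-1 at trap-4 and F10G7.9 at tsn-1. Of the 10 strongest nuclear peaks, 7 had a gene of the 4 secretory lists in reach, as had 10 of the first 20, 24 of the first 100 and 63 (2.68%) of all 2349. Of the 20 strongest peaks of the whole list, 10 were mitochondrial. The nuclear ranks were therefore used after the data were seen.

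Some peaks of the first 20 lay near further genes beyond the promoter window, or in no window at all. The sixth nuclear peak (4933; IV, 14824605 to 14825399) was assigned to rps-18, 673 bp away, while its summit lay in a noncoding or untranslated exon of sec-61.A, 258 bp downstream of that gene's 5′ end. The sixteenth (2049; IV, 10221966 to 10222720) was assigned to C24F3.2, 128 bp upstream of its 5′ end, and its summit lay 1124 bp upstream of tram-1, a translocation gene. The peak at nuclear rank 17 (I, 9381088 to 9381989) lay in an intron of ppfr-1, and the one at rank 18 (X, 15842383 to 15842989) in a coding exon of F59F4.3. The tagged gene itself, let-607 (I, 6574004 to 6585510), had neither an IDR peak nor a pooled relaxed peak in its promoter window. Its nearest IDR summit was 9375 bp upstream and its nearest relaxed summit 7698 bp upstream. sec-61.A and tram-1 were singled out after their values were seen.

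All 4 lists of secretory pathway genes were bound more often than other protein-coding genes. Of all 19985 protein-coding genes, 1550 (7.76%) had an IDR summit in the window. Of the genes of COPI, COPII and ER-Golgi transport, 24 of 32 were bound (odds ratio 36.2, 15.7 to 93.4; two-sided Fisher's exact test, adjusted p = 1.2e-19). They included ile-2, sec-24.1 (signal 1515), syx-5 (1393) and sar-1 (1237), whereas arf-1 had no peak and copb-1 and gbf-1 had relaxed peaks only. Of the ER protein folding and unfolded protein response genes, 19 of 27 were bound (28.6, 11.9 to 75.6; adjusted p = 6.4e-15 by the exact test), led by hsp-3, enpl-1, pdi-1 and xbp-1. Of these, cnx-1 and ckb-2 had no peak in their windows, and der-2 had only a relaxed peak. Signal peptide recognition and ER translocation had 11 of 21 bound (13.2, 5.07 to 34.6; adjusted p = 5.5e-07 by the exact test), with trap-2, sec-61.G, trap-3 and sec-61.B highest. Of this list, emc-1, emc-2 and emc-3 lacked an IDR peak. N-glycosylation had 9 of 31 (4.89, 1.98 to 11.1; adjusted p = 0.0013 by the exact test), among them mans-3 (1549), dad-1 (539), dpm-3 (296) and ostd-1 (185). Genes aagr-3 and aagr-4 had relaxed peaks at pooled ranks 2506 and 2611, below the IDR threshold, and algn-1 one at rank 6763. When genes sharing their summit with a neighbour were left out, a step that removes only bound genes, the translocation list had 1 of 11 bound (odds ratio 2.24, adjusted p = 0.59, exact test) and the N-glycosylation list 3 of 25 (3.06, adjusted p = 0.20, exact test). Among genes whose window overlapped no other gene's window, a setting chosen after the data were seen, they had 1 of 4 (6.33, adjusted p = 0.34) and 3 of 19 (3.57, adjusted p = 0.16, exact tests). Against only genes with a relaxed peak, the odds ratios of the first 3 lists were 22.5, 17.8 and 5.11 (adjusted p = 5.9e-12, 4.2e-09 and 0.0030, exact tests), and N-glycosylation had 2.57 (adjusted p = 0.095 by the exact test). With each peak given only to its nearest 5′ end, N-glycosylation had 2.74 (adjusted p = 0.0998, exact test).

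Binding also lay at genes of protein synthesis and turnover, while genes for cuticle and neuropeptides had few peaks. Of the cytosolic ribosomal protein genes, 44 of 80 were bound (odds ratio 14.9, 9.36 to 23.9; Fisher's exact test, adjusted p = 7.9e-27), with rps-18, rpl-1 (signal 1128), rpl-3 (1034) and rpl-20 (911) highest. The summit counted for rps-18 lay 673 bp upstream of it, in a noncoding or untranslated exon of sec-61.A, a gene of the translocation list. Against only genes with a relaxed peak, the odds ratio of the ribosomal list was 5.74 (adjusted p = 5.9e-12, exact test). By the same exact test, higher shares were also found for the proteasome (10 of 33; 5.20, adjusted p = 0.00050; rpn-3, rpn-11, rpn-1 and pbs-1), for the cytosolic and mitochondrial heat shock genes (7 of 25; 4.64, adjusted p = 0.0056; hsp-110, hsp-60, hsp-1 and dnj-19) and for the mitochondrial respiratory chain (8 of 34; 3.67, adjusted p = 0.0081; atp-3, ucr-2.2, atp-1 and mev-1). The vacuolar ATPase and lysosome list had 7 of 28 (3.98, adjusted p = 0.0085, exact test; vha-1, vha-12, vha-13 and cpl-1). The bZIP transcription factor genes had 8 of 26 (5.31, adjusted p = 0.0016, exact test), led by xbp-1, cebp-1, zip-11 and atf-4, and 3.71 against only genes with a relaxed peak (adjusted p = 0.038, exact test). Cuticle collagen genes were bound in 4 of 176 cases (0.275, adjusted p = 0.0081; col-38, col-71, col-63 and col-185) and neuropeptide and insulin genes in 3 of 143 (0.253, adjusted p = 0.012, exact tests; ins-39, nlp-36 and nlp-40). All tests here were two-sided Fisher's exact tests adjusted over the 22 lists. Lists could share a peak. The peak at rpn-3 was also that at hsp-110, and the peak at rpn-1 was also that at ribo-1 of the N-glycosylation list. The proteasome, heat shock, respiratory, collagen and neuropeptide calls were lost when genes sharing a summit were left out (odds ratios 1.95, 1.24, 2.59, 0.258 and 0.478; adjusted p = 0.50, 0.69, 0.25, 0.10 and 0.50, exact tests). They were also lost against only genes with a relaxed peak (odds ratios 1.95, 2.88, 1.41, 0.342 and 0.307; adjusted p = 0.20, 0.13, 0.52, 0.095 and 0.11, exact tests), where the vacuolar ATPase call was lost too (1.44, adjusted p = 0.56). The collagen odds ratio stayed about as low in both while its p missed the threshold. Among genes whose window overlapped no other's, the respiratory call held (11.4, adjusted p = 0.018, exact test) and the other 4 were lost (odds ratios 3.16, 1.90, 0.304 and 0.319; adjusted p = 0.47, 0.59, 0.21 and 0.27, exact tests). Without replicate 1 the neuropeptide list was also not called (odds ratio 0.357, adjusted p = 0.060 by the exact test), and without replicate 2 its odds ratio was 0.167 (adjusted p = 0.0032).

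Of the 6 lists of tissue markers, that of the intestine was the one that differed from other genes, and the lists were not tested against each other. Of its genes, 9 of 19 were bound (odds ratio 10.8, 3.86 to 29.5; adjusted p = 2.0e-05 by Fisher's exact test), at peaks of median nuclear rank 1455. The odds ratio was 6.03 with the stricter signal threshold, which left 4 of 19 bound, and 5.57 against only genes with a relaxed peak (adjusted p = 0.021 and 0.0055, exact tests). The bound genes included the vitellogenin genes vit-6, vit-2, vit-5 and vit-3, which encode yolk proteins and had summits 75, 75, 97 and 109 bp upstream of their 5′ ends. These belong to 1 gene family, so members of this list are not independent, as the exact test assumes. No cause of the difference was tested. No neuron marker (0 of 24), hypodermis marker (0 of 21) or germline marker (0 of 34) was bound, which allows bound shares of up to 14.2%, 16% and 10.3%, and none of these lists differed from other genes by the exact test (adjusted p = 0.33, 0.49 and 0.16). Body wall muscle markers had 1 of 22 bound (unc-112), pharynx markers 1 of 13 (pha-4), the basement membrane list 1 of 20 (nid-1), histones 2 of 72 (his-37 and his-72) and autophagy genes 3 of 25 (lgg-2, lgg-1 and epg-8). Adjusted p for these lists was 1, 1, 1, 0.25 and 0.51 (exact tests). The autophagy odds ratio of 1.62 became 2.37 without replicate 1 and 2.96 without replicate 2 (5 of 25, adjusted p = 0.064, exact test), and that of histones, 0.339, became 0.540 and 0.514, none of them called. Without replicate 2 no pharynx marker was bound. Phospholipid and fatty acid synthesis genes had 6 of 32 bound (2.75, 0.925 to 6.85; adjusted p = 0.054 by the exact test), among them cept-2, nhr-49, dgat-2 and pmt-1. That list passed the threshold when genes sharing a summit were left out (4.32, adjusted p = 0.030, exact test). In all, 13 of the 22 lists passed, 11 higher and 2 lower. That count was 6 when the background was the genes with a relaxed peak and 7 when genes sharing a summit, all of them bound, were left out. It was also 7 among genes whose window overlapped no other's, a setting chosen after the data were seen.

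**Figure D1:**
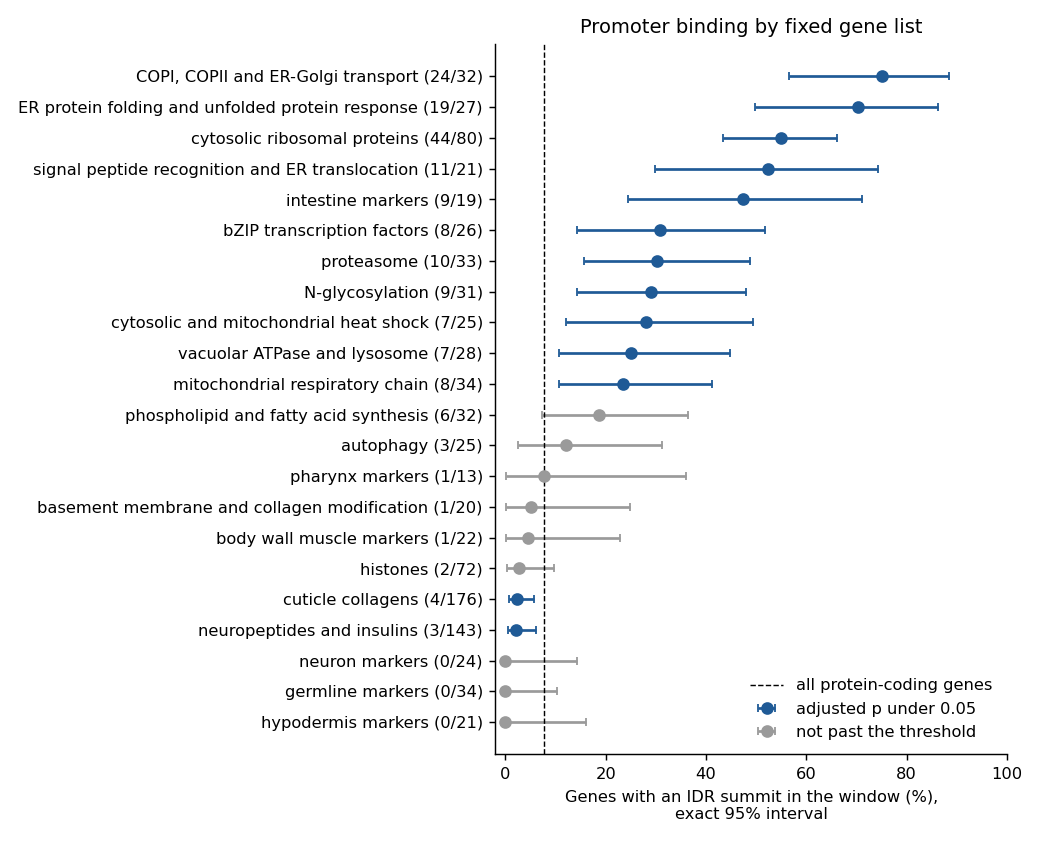
Percent of genes of each fixed list with an IDR summit in the promoter window (points, with exact 95% intervals; bound and total members in brackets), against all protein-coding genes (dashed line, 7.76%). The lists of ER-Golgi transport (24 of 32) and ER protein folding (19 of 27) lie highest.

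The CRE core TGACGT, the recognition core of CREB-type bZIP factors, was present within 50 bp of 195 IDR summits (8.22%, 7.15 to 9.40), against 3.06% of flanking windows of the same peaks, a ratio of 2.69 (exact binomial test, adjusted p = 1.9e-13 over 14 fixed sequences). Its longer form TGACGTGG stood at 1.90% of summits against 0.295% (ratio 6.43, adjusted p = 4.7e-07, exact test), and GACGTG at 7.04% against 2.19% (adjusted p = 3.3e-14). Against shuffled centre sequences of the same dinucleotide content, the background was 5.10% for TGACGT and 4.76% for GACGTG, with ratios of 1.61 and 1.48 (adjusted p = 2.3e-05 and 0.0013, exact tests). The control string TGCAGT, which is TGACGT written backwards, also passed against that background (6.58% against 4.55%, ratio 1.44, adjusted p = 0.0031, exact test). Shuffling therefore set TGACGT and GACGTG little apart from the control. The palindrome TGACGTCA was at 0.970% against 0.464% of flanks and did not pass (exact test, adjusted p = 0.19), but passed against the shuffled background (0.169%, ratio 5.75, adjusted p = 0.00054, exact test). Examples were CGCACCATGACGTCGTTTAC over the summit at serp-1.1, CGTATGCTGACGTGTCAATA beside that at pdi-1, TGGGAAATGACGTCAAGAGG at xbp-1, CAGTCGCTGACGTGGACCAA at crt-1 (calreticulin) and TCGGAGATGACGTGTATTAG at hsp-4 (a BiP-type chaperone). Each is written with TGACGT on the given strand, and crt-1 and hsp-4 were chosen after their values were seen. No TGACGT lay within 50 bp of the summits at ile-2 and trap-2, sec-61.G, trap-3 and sec-61.B, hsp-3, trap-1, or enpl-1 and imp-2. Those peaks held nuclear ranks 1, 3, 4, 5, 7 and 8, and the hsp-4 peak held nuclear rank 703. Of 226 TGACGT sites near nuclear summits, 110 (48.7%, 42.0 to 55.4) were followed by G, against 22.1% (16.13 to 29.0) of 172 flank sites, a comparison made after the data were seen.

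Other sequences were raised at summits as well. CCACG, part of the ER stress element, was near 23.5% of summits against 7.63% of flanks, the E-box CACGTG near 8.31% against 1.69%, GATAAG, the site of GATA factors, near 11.97% against 4.26%, and GAGAGA near 17.7% against 6.77% (ratios 3.08, 4.93, 2.81 and 2.61; adjusted p = 6.1e-50, 1.7e-25, 3.1e-19 and 6.0e-28, exact binomial tests). Against the shuffled background of 12.7%, 2.57%, 3.37% and 8.35%, the ratios were 1.85, 3.23, 3.55 and 2.12, and all 4 passed. CTCCGCCC was near 1.01% against 0.337% (adjusted p = 0.021), a call lost without replicate 1 (0.927%, adjusted p = 0.078, exact tests). TGACTCA, ATTGCATCA and TTTCGCGC did not pass (exact tests, adjusted p = 0.93, 1 and 0.29). The control string TGCAGT, TGACGT written backwards, was also raised (6.58% against 3.50%, adjusted p = 6.0e-05), and the control ACTGCAGT was not (0.253% against 0.105%, adjusted p = 0.59, exact tests). Among all 6-mers, 514 were higher and 342 lower than in flanks at adjusted p under 0.05. Those of highest ratio in at least 5% of peaks each contained a CG dinucleotide: ACGCAG (12.06% against 1.88%), GCGCGC, GACGCA, CACGCG, GCGCCA, GCGGCC, CGCGGC, CACGTG, GCGCAC and CGTGGC. With shuffled centre sequences of the same dinucleotide content as background, 264 6-mers were higher and 393 lower.

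**Figure D2:**
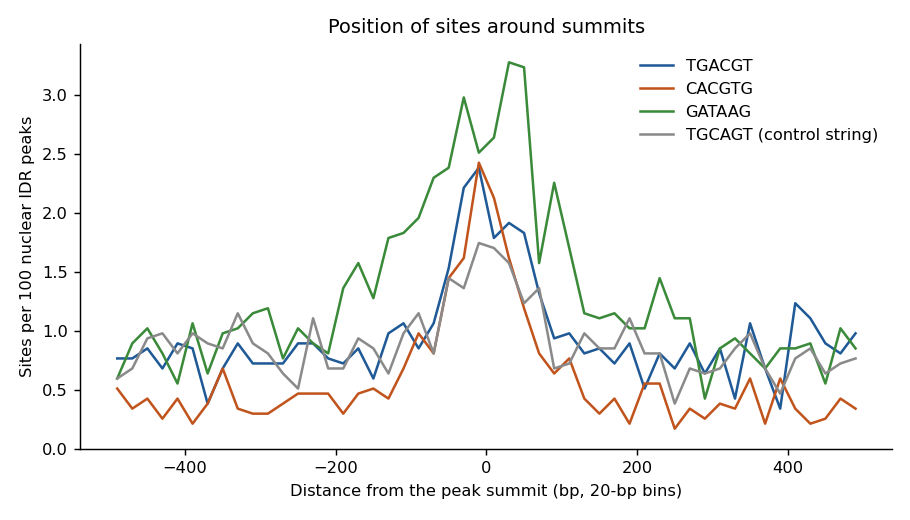
Sites per 100 nuclear IDR peaks (vertical axis) in 20-bp bins by distance from the summit (horizontal axis, bp), for TGACGT, CACGTG, GATAAG and the control string TGCAGT (lines). All 4 lines are highest near the summit.

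Peaks with TGACGT ranked higher by signal than those without. In 4 equal groups by IDR signal from the strongest down, TGACGT was near 12.8%, 7.08%, 7.76% and 5.23% of summits. With rank counted upwards from the weakest peak, the mean rank was 1400.3 for peaks with TGACGT and 1167 for those without, a difference of 233 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Among the 50 strongest nuclear peaks, 13 (26%, 14.6 to 40.3) held TGACGT and 24 (48%, 33.7 to 62.6) held CCACG, against 6.60% and 19.4% of the 1349 weakest. GATAAG was near 8% of the 50 strongest summits (2.22 to 19.2) and 13.3% (11.6 to 15.3) of the 1349 weakest. The control string TGCAGT fell with signal as well, from 14 of the 50 strongest (28%, 16.23 to 42.5) to 4.82% of the 1349 weakest. These p-values run over peaks of 1 pooled list and not over replicates.

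**Figure D3:**
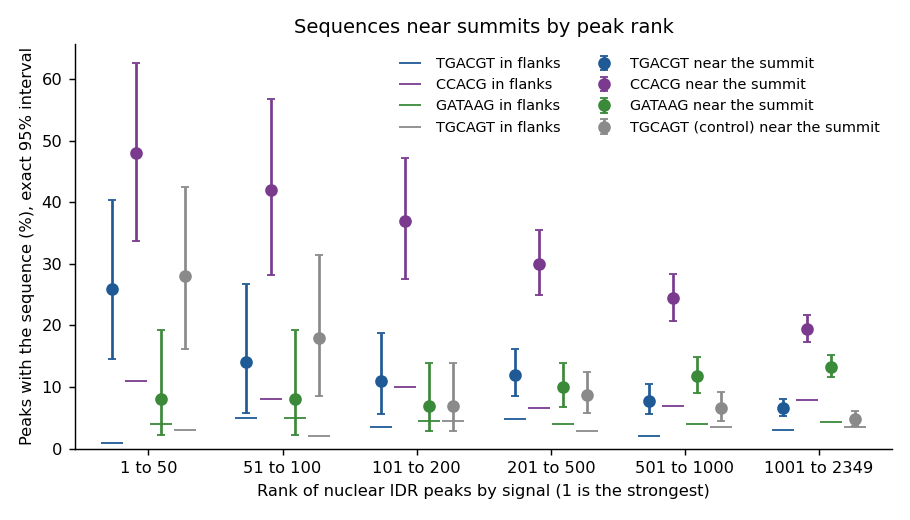
Percent of nuclear IDR peaks with TGACGT, CCACG, GATAAG or the control string TGCAGT within 50 bp of the summit (points, exact 95% intervals) and in flanks (dashes), by rank of signal. From the 50 strongest peaks to the 1349 weakest, TGACGT falls from 26% to 6.60% and TGCAGT from 28% to 4.82%.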

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

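The tests of relaxed peaks below the IDR threshold were chosen after the data were seen. A signal appeared in peaks outside the authors' final list: among the nuclear peaks at pooled relaxed ranks 2373 to 4744, TGACGT was near 5.19% of summits (4.33 to 6.16) against 2.74% of their flanks (exact binomial test, adjusted p = 0.0010). At ranks 4745 to 9488 the share was 3.88% against 3.02% (adjusted p = 0.052, exact test), and from rank 9489 on 3.34% against 3.11% (adjusted p = 0.98). Of the 48 genes of the secretory lists without an IDR peak, 29 (60.4%) had a relaxed peak below the threshold in their window, against 31.0% of other genes without an IDR peak, a difference that was not tested. Among them were aagr-3 and aagr-4 at pooled ranks 2506 and 2611. Housekeeping lists had many such genes as well. Of 80 ribosomal, 33 proteasome and 34 respiratory genes, 73, 29 and 29 had a pooled relaxed peak of any rank in their window. Only 44, 10 and 8 of them had an IDR peak. The difference is therefore not particular to the secretory lists.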

How the results depend on the processing

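Leaving out mitochondrial peaks, peaks at tRNA, snoRNA or snRNA genes, and genes whose window overlaps another gene's window were tests chosen after the data were seen. Of the recomputed values of the main comparisons, 50 stayed on their side of the threshold or within the allowed spread and 8 moved. Without each replicate in turn, the promoter share was 50.6% to 52.7%, the list count 12 to 13, and the rank difference of peaks with TGACGT 188 to 199. The ratio of the promoter share to random placements depended on the window. It was 3.74 with 500 bp upstream and 100 bp downstream (42.2% against 11.3%). With 2000 bp upstream and 500 bp downstream it was 1.64 (64.6% against 39.5%). The overlap of replicate lists was 42.6% with 50% reciprocal overlap, 31.8% for summits within 100 bp and 73.5% for the strongest 2372 peaks of each, where rho was 0.728. The first 2 follow from the stricter rule, and for the strongest peaks the cause was not tested. The stricter signal threshold left 1186 IDR peaks by construction. The list count was 6 against genes with a relaxed peak, 7 with genes sharing a summit left out and 7 with genes whose window overlaps another's left out. These tests held fewer genes, and leaving out genes that share a summit removes only bound ones by construction; beyond that the cause was not tested. For single lists and sequences called in the report, 195 recomputed values kept the call and 33 lost it, and none turned direction. For those not called, 130 stayed so in the same direction, 5 gained a call and 18 turned direction without one. The turns among lists were pharynx (odds ratios 1.04 without replicate 1, 1.06 without small RNA peaks, 1.29 with the 500 bp window, 1.18 by nearest 5′ end, 3.70 against relaxed peaks, 1.87 without shared summits and 1.90 with separate windows, but 0 and no turn without replicate 2), autophagy (0.739 against relaxed peaks), and basement membrane and body wall muscle (1.18 and 1.07 without shared summits, 1.12 each with separate windows). Those among sequences were TGACTCA (1.01% without replicate 2 and 2.28% in 100 bp, but 0.885% and no turn without replicate 1), ATTGCATCA (0.0843% in 25 bp, 0.422% in 100 bp), TTTCGCGC (0.169% in 25 bp) and ACTGCAGT (0.253% in 100 bp); the cause was not tested. Beyond the losses given in the report, the stricter signal threshold ended the calls of the vacuolar ATPase (odds ratio 2.71), proteasome (2.26), collagen (0.257) and neuropeptide (0.158) lists, and that of CTCCGCCC (1.10%, adjusted p = 0.15, exact test). Assignment to the nearest 5′ end ended those of the heat shock (2.71) and neuropeptide (0.407) lists, and leaving out genes with under 300 bp upstream ended those of the vacuolar ATPase (3.10), respiratory (3.21) and collagen (0.396) lists; the cause was not tested. The phospholipid list gained its call with the window of 2000 bp (3.39) and without peaks at small RNA genes (2.93), TGACGTCA against the shuffled background (0.970%) and TTTCGCGC with windows of 100 bp (1.69%, adjusted p = 0.026, exact test). ER-Golgi transport (odds ratios 18.5 to 43.2), ER folding (17.8 to 39.0), ribosomal proteins (5.74 to 17.6), intestine markers (5.57 to 20.3) and bZIP genes (3.71 to 8.93) kept theirs in all 12 alternatives. Without read counts, the depth below which peaks were missed is unknown.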

Other observations

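Chosen after the data were seen were the tests of noncoding gene classes, of tRNA genes, of GATAAG, of strings with the same bases, of the control string at secretory genes, of mitochondrial peaks, of the strongest peaks without TGACGT, of the excess in the weakest group without each replicate, of genes with separate windows, and of secretory against housekeeping genes, for peaks with TGACGT and head to head. Genes for small RNAs carried many IDR peaks. Of 612 nuclear tRNA genes, 224 (36.6%) had a summit within 100 bp, from 212 peaks against a mean of 4.43 in random placements (47.9 times, two-sided permutation p = 0.002, the smallest possible; adjusted p = 0.0033 over the 10 noncoding classes of the annotation, all of which were examined). Summits lay near snoRNA genes in 73 cases (27.6 times random), near snRNA genes in 19 (24.17 times), near the class annotated as ncRNA in 349 (6.18 times) and near miRNA genes in 6 (3.38 times, permutation test, adjusted p = 0.014). Pseudogenes (0.244 times random) and piRNA genes (0.364 times) had fewer (permutation tests, adjusted p = 0.0033 each). For lincRNA (1.83 times, adjusted p = 0.10), antisense RNA (2.52 times, 0.065) and rRNA genes (0 peaks, adjusted p = 1) no difference was called by permutation. No tRNA peak was among the 100 strongest nuclear peaks, the best holding rank 283, whereas 24 of those 100 had a secretory gene in reach. Of the other raised classes, ncRNA genes had 14 of those 100, with best rank 4. The snoRNA and miRNA genes had 1 each, at ranks 15 and 33, and snRNA genes 0.

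GATAAG and TGACGT were hypothesised to mark different peaks, and the data went against this. GATAAG was near 35 of 195 nuclear summits with TGACGT and 249 of 2154 without (odds ratio 1.67, 1.10 to 2.49). Peaks with GATAAG ranked lower by signal (mean rank 1048 against 1192, counted upwards from the weakest; permutation p = 0.00093), unlike peaks with TGACGT. Of the 10 peaks in reach of intestine markers, 3 held GATAAG.

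Most IDR peaks lacked TGACGT, and 3 explanations were weighed for these. Weak peaks let in by the threshold were argued against as the whole cause, since 84.6% (78.8 to 89.4) of the 195 strongest nuclear peaks, as many as held TGACGT in all, lacked it; for the weaker peaks this stays open, as the excess of TGACGT over flanks in the weakest group was 0.237 of that in the strongest (0.033 to 0.517), and 0.341 and 0.474 without replicates 1 and 2, too wide a range to decide. A shorter form of the site could account for part of them, since ACGT was 1.43 times as frequent near their summits as in flanks (1.31 to 1.56), below the 1.5 set in advance but above 1, so this stays open. Binding at accessible promoters without sequence choice stays open as well. Of the peaks without TGACGT, 51.3% (49.2 to 53.5) lay at promoters, against 57.9% (50.7 to 65.0) of peaks with it, intervals that overlap. A promoter share does not measure sequence choice, and accessibility was not analysed, so this decides nothing. No biological explanation was tested, since there was 1 group.

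The secretory lists together had an odds ratio of 16.22 (10.9 to 24.23), and 3 technical explanations were set against it. Windows shared with neighbouring genes were argued against as the whole cause, since the odds ratio was 15.7 (8.72 to 27.9) among genes whose window overlapped no other gene's, whereas the 14.5 (8.80 to 23.4) with genes sharing a summit left out decides nothing, because that step removed only bound genes. Peaks of any kind, rather than those with the site, stay open: the odds ratio was 9.30 (6.20 to 13.9) from peaks without TGACGT (45 bound genes) and 30.8 (16.96 to 53.3) from peaks with it (18 genes), a gap as wide as the one set in advance, but peaks with the control string TGCAGT gave 35.1 (19.2 to 60.98), so the gap was not specific to the site, although peaks with TGACGT and without TGCAGT still gave 25.7 (13.4 to 46.2). Generic binding at promoters of highly expressed genes cannot be told apart over all peaks. The interval of the housekeeping lists (8.99, 6.35 to 12.7) overlapped, and expression was not analysed here. The direct comparison of secretory with housekeeping lists (1.80, 1.06 to 3.05, Fisher's exact p = 0.024) went against equal binding. However, the ribosomal list alone had 44 of 80 bound (55%), close to the 63 of 111 (56.8%) of the secretory lists. The lower housekeeping share came from the proteasome (10 of 33) and respiratory (8 of 34) lists, so this comparison decides nothing about generic binding. From peaks with TGACGT, the housekeeping lists had 2.95 (0.595 to 8.98), on 3 bound genes, against 30.8 for the secretory lists. Whether housekeeping promoters hold TGACGT less often was not tested, so this gap decides nothing about generic binding. Peaks with TGCAGT separated the lists as well (35.1 against 5.69, 1.79 to 13.95), so the gap cannot be credited to TGACGT. TGCAGT was itself raised, at 23% of the 100 strongest nuclear summits against 2.5% of flanks. It is therefore no inert control, and its gap does not exclude a part for TGACGT either. From peaks without TGACGT the housekeeping lists had 9.23, close to the secretory 9.30.

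For the tRNA peaks 3 technical explanations were tested and all remain open, so no biological claim is made. Recovery of these loci without the site is consistent with TGACGT near only 0.943% (0.114 to 3.37) of their summits, against 2.12% of their flanks and 9.03% of other nuclear peaks. Weak peaks let in by the threshold may account for part, as a tRNA gene was more frequent in the weakest than in the strongest of 4 equal groups by signal (odds ratio 4.92, 2.69 to 9.63), although the shares from the strongest down, 2.38%, 9.88%, 13.1% and 10.7%, set only the strongest group apart. Reads shared between identical copies may also contribute, since genes with an identical copy had a peak more often (1.81, 1.18 to 2.83), though 26.6% of the 143 single-copy genes had one as well. Identical copies are not independent of each other, so this interval may be too narrow.

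The mitochondrial genome had 90.9% of its 13794 bp under pooled relaxed peaks, and 0 of its 23 IDR summits had TGACGT near, which allows a share of up to 14.8%. Among 180 strings with the bases of TGACGT, TGCAGT was at 23% of the 100 strongest nuclear summits and TGACGT at 20%, the places 3 and 4 of those strings, against a median of 3%. Over all nuclear summits TGACGT held place 2 (8.30%) and TGCAGT place 11 (6.56%).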
